A study of Mus musculus with 4 samples.

How the data were processed

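Flag ChIP-seq was carried out on mouse iMN-ESCs, embryonic stem cells that carry a doxycycline-inducible (Dox-inducible) transgene for a Flag-tagged fusion of the LIM-homeodomain factors Isl1 and Lhx3. Per the labels, there were 4 libraries in 2 numbered sets, each set holding 1 library with Dox and 1 without. Nothing in the labels says whether the sets were separate cultures. Per the labels' protocols, embryoid bodies received retinoic acid at 0.5 µM alone for 2 days, then retinoic acid with or without Dox at 2 µg/mL for 4 days. LIF at 1000 units/mL was given for the 16 hours before harvest.

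The submitters' processing notes name BWA 0.5.8a and the genome build mm9, which is NCBIM37. The peak caller, its threshold, the scaling of the scores and any pooling of the sets are not given in the sources used here. The authors deposited 1 peak list for the whole series. Its ChIP score and its background score per peak are deposited values with no stated scale, treated here as the unit score. Its ChIP tags are a deposited whole-number count of tags per region, and the peaks of 1 region carry the same count. What the background score was measured on is not stated per the file headers. The list held 2455 peaks in 2302 regions, each peak with a 500 bp window around its maximum, and 0 windows ran past a chromosome end of mm9. A single peak on the mitochondrial genome was left out, which left 2454 peaks in 2301 regions. No column gives a value per library or per set, so the total depth of each library is unknown and the spread between sets could not be measured. A p-value here compares peaks of 1 list with each other, with random positions or with flanking sequence. The score of a peak is the authors' value and was used only to describe, rank or filter peaks. Intervals are 95% intervals. Those of shares and counts are exact binomial (Clopper-Pearson) or exact Poisson intervals, those of odds ratios are exact conditional intervals, and all of these cover counting error only. Ratios of mean background scores and the median ratio of background to ChIP score have bootstrap intervals from 10000 draws. None covers the spread between sets.

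Coordinates are 1-based on mm9. Genes came from GENCODE release M1 (Ensembl 65) on the same build, with 37273 annotated genes, of which 22367 are protein-coding. Each peak maximum was assigned to the gene with the nearest transcription start, and 37220 genes could receive a peak. Distances are negative upstream of the start. A gene's territory is the set of bases nearest to its starts. Of 322 list genes, 319 matched by symbol, 2 by an older symbol or an identifier from a RefSeq table of GRCm38.p6, and 1 did not match (Slc18a3). Where a symbol had several gene records, the longest protein-coding one was used.

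The following choices were made before the data were examined. Peaks per chromosome were compared with the chromosome's share of genome length by exact binomial tests. Positions and clustering were compared with 1000 random placements on the same chromosomes, for which the smallest possible p is 0.002. There were 15 gene lists: motor neuron transcription factors, cholinergic transmission, motor column and pool, spinal interneuron transcription factors, JAK-STAT pathway, axon guidance, ion channels and synapse, Notch pathway, retinoic acid pathway, pluripotency, glia, endoderm and liver, blood, skeletal muscle and housekeeping. Each list was tested by a two-sided Fisher's exact test against all other genes and against 10000 random lists matched on territory in 20 bins, for which the smallest possible p is 0.0002. Peak strength was compared by median rank with 100000 permutations, or by the exact distribution where a list had fewer than 10 peaks. For 18 motifs, the share of peaks with a match in 200 bp centred on the maximum was compared with 200 bp flanks 1 kb to each side by Fisher's exact test. All tests were two-sided, with Benjamini-Hochberg adjustment within each family and a threshold of 0.05. The genes named in the text follow a fixed rule: the 10 strongest peaks, up to 4 members per list with the strongest peak and the first 2 members without one, the 5 genes with most peaks, and always Isl1, Lhx3, Mnx1, Slc18a3, Chat, Stat3 and Socs3. Some genes that this rule selects are not reported here. Other genes are named only as the host or the nearer neighbour of such a peak, or where the text says that they were chosen after their values were seen.

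The fixed alternatives were the 50% and the 25% of peaks with the highest scores, the share of annotated genes per chromosome, protein-coding genes alone, peaks within 10 kb or 100 kb of a start, other distances, other windows, dinucleotide-shuffled sequence, strata of GC content, the strict STAT site, 1 added to each score and ChIP tags as the strength. Added after the data were seen were 1 peak per region, peaks with a background score under 10% of the ChIP score, the share of protein-coding genes per chromosome, all 6-mers, spacings of up to 12 bp between TAAT and ATTA cores, motif position, regions per gene territory, windows of 10 Mb and the motor neuron list without Isl1. The fixed plan also held the agreement between the 2 sets and the signal with Dox against without Dox, which were left out because the peak list used here holds no value per library.

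The computation was changed at some points after first results had been seen. Symbols with several gene records first entered a list more than once and were then reduced to 1 record, which altered the axon guidance list and lists with Pou3f1, Ebf1 or Scn8a. The numbers of lists called with all annotated genes, 4 by Fisher's exact test and 3 by the matched test, were the same before and after, while with protein-coding genes alone the matched test called 5 lists before and 4 after. For lists with fewer than 10 peaks a Fisher's exact test on strength was replaced by the exact distribution of the median rank, as the plan had stated. An alternative was counted as reversed at any change of direction, and infinite odds ratios were left out of the alternatives.

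The tests of peaks per chromosome, gene lists, motifs, clustering and peak strength were tried on simulated data, and the other tests were not. For peaks per chromosome, 100% of planted changes were called, and 5.25% of draws with nothing planted gave any call. These draws placed each peak independently, so they do not give the rate of false calls for peaks that come in groups. For gene lists, 100% of draws with 8 of 20 genes planted were called, against 2% of draws with any call when nothing was planted. For motifs, 0 of 18 motifs were called between flanks, and a relaxed STAT site planted in 2% of windows was called in 100% of 20 draws at an unadjusted p under 0.05, against 0% when planted in 1%. Both sides of that simulation were flanks, so its sensitivity does not carry over to peaks, whose GC content was higher than that of flanks. For clustering, permutation p was 0.736 with random positions and 0.00995 with 200 planted pairs. For peak strength, 2.5% of draws without a shift and 99.5% of draws with 30 shifted peaks were called, and the exact test called 5.25% of draws without a shift. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6, pysam 0.24.0, samtools 1.23.1 and matplotlib 3.10.9 were used.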

Results

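Binding of the Flag-tagged Isl1-Lhx3 fusion was mapped by ChIP-seq in mouse iMN-ESCs that were differentiating under retinoic acid, with Dox to switch the fusion on (n = 2 libraries) and without Dox (n = 2 libraries). Isl1 and Lhx3 are LIM-homeodomain transcription factors of motor neuron development. LIF, a cytokine that signals through JAK and STAT3, was added for the last 16 hours. The deposited list gives 2454 nuclear peaks in 2301 regions, with 1 ChIP score, 1 background score and 1 tag count each. No value per library was given, so the list was described as it stands and no difference between libraries was tested.

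The strongest peaks lay mostly inside genes. The top peak (chromosome 14, 77650320 to 77650819 on mm9) lay in an intron of Enox1, 1.57 kb from a start of the predicted gene Gm10132, with a ChIP score of 321.18, a background score of 5.43 and 390 tags (352 to 431, 95% Poisson interval). The second (chromosome 14, 68360095 to 68360594) lay in an untranslated region of Kctd9, 2.94 kb upstream of Gnrh1, the gene of gonadotropin-releasing hormone, with a score of 266.04. Introns of Wwp2 (263.37), Ankrd55 (254.27), Accn2 (251.59), Slc35f3 (218.67), Lats2 (191.64) and Dmxl2 (184.95) also held peaks of the top 10. The remaining 2 were intergenic, near Paqr9 (204.48) and Gm11828 (204.22). Across the list the ChIP score ran from 29.98 to 321.18, with a median of 40.95 and quartiles of 34.26 and 54.07. Tags per region ran from 10 to 491, with a median of 30.

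The only control measure in the list was the background score. It was far below the ChIP score at nearly all peaks: 2321 of 2454 (94.6%, 93.6 to 95.4) had a ChIP score at least 10 times the background score, and 762 (31.1%, 29.2 to 32.9) had a background score of 0. At Accn2, Chat and Mnx1 the strongest peak had a background score of 0. A background score of at least 20% of the ChIP score was found at 18 peaks (0.733%). With 1 added to each score the share at 10 times or more was 88.5%. The source of the background score is not given, so these shares are not a comparison of with Dox against without Dox. The list holds called peaks only, and no background score exceeded 32.5% of the ChIP score. As the caller's threshold is not given, a low background score may in part be a condition of being listed.

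The genes of the fusion's own components and of the motor neuron programme held peaks of differing strength. Near Lhx3 the peak of rank 18 (chromosome 2, 26050065 to 26050564, intergenic) had a score of 162.46 and lay 8.07 kb from its start, although the noncoding gene Gm13553 was nearer. Near Mnx1 (Hb9), a motor neuron homeobox gene, a peak of score 111.61 lay 6.75 kb upstream (chromosome 5, 29811563 to 29812062, intergenic), with a U6 small nuclear RNA gene nearer. Chat, which encodes choline acetyltransferase, held an intronic peak of score 87.25 (chromosome 14, 33256618 to 33257117) at 22.2 kb from its start, with the noncoding gene Gm2990 nearer. Isl1 held 2 peaks, of score 61.56 and 39.61 (the stronger at chromosome 13, 117091651 to 117092150), and both maxima lay in coding exons, where 22 of all peaks (0.896%) lay. The transgene also carries Isl1 coding sequence, and the list does not show whether these tags came from it. Slc18a3, the vesicular acetylcholine transporter gene, had no record in the annotation used and was not analysed here, so a peak nearer to it than to Chat would not be recognised. Stat3 and Socs3 had no assigned peak.

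Gene lists showed where peaks gathered. Of 37220 genes, 1938 had at least 1 peak. Pluripotency genes had a peak in 8 of 21 cases (38.1%, 18.1 to 61.6), against 5.19% of other genes. The odds ratio was 11.2 (4.03 to 29.3), with an adjusted p of 4.4e-05 by Fisher's exact test and 0.0030 against matched random lists. Prdm14 (86.18), Esrrb (56.21, 5 peaks), Zfp42 (54.07) and Sall4 (40.68) had the strongest peaks among them, whereas Pou5f1 and Nanog had none. Axon guidance genes had a peak in 12 of 36 cases (33.3%, 18.6 to 51.0), with an odds ratio of 9.15 (4.16 to 19.1), an adjusted p of 2.2e-06 and a matched p of 0.0100 after adjustment. Slit3 (74.67), Nrp2 (70.66), Sema3e (67.45) and Sema3f (59.95), which encode guidance cues and a receptor, led that list, and Slit1 and Slit2 had no peak.

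Genes of cholinergic transmission had a peak in 4 of 13 cases (30.8%, 9.09 to 61.4). The odds ratio was 8.10 (1.82 to 29.1), with an adjusted p of 0.0134 by Fisher's exact test and 0.066 by the matched test. The genes were Acly (61.56), which makes the acetyl-CoA used for acetylcholine, the transporter-like Slc10a4 (42.82, -0.064 kb from its start) and the nicotinic receptor genes Chrna5 (37.47) and Chrna4 (35.33), while Slc5a7 had none. The housekeeping list, included as a control, also passed, with 5 of 18 genes (27.8%, 9.69 to 53.5), an odds ratio of 7.02 (1.96 to 21) and adjusted p of 0.0092 and 0.0030 by the 2 tests. Its genes with the strongest peaks were Gusb (92.07), Tuba1b (75.74), Ywhaz (53.26) and Gapdh (34.79), and the Gusb and Gapdh peaks lay inside the neighbouring genes Vkorc1l1 and Iffo1. Actb and Hprt had no peak. Since this control list passed both tests, a call for another list does not by itself show binding tied to that list's function.

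Motor neuron transcription factors had a peak in 4 of 20 cases (20%, 5.73 to 43.7), with an odds ratio of 4.56 (1.11 to 14.1) that did not pass (Fisher's exact test, adjusted p = 0.055, matched p = 0.47 after adjustment). Neurog2 (91.0, 4 peaks in its coding exon), Isl1 (61.56) and Lmo4 (55.67) were among those with a peak, and Isl2 had none. The side of the threshold on which this list fell depended on the choices made. With protein-coding genes alone, Lhx3 and Mnx1 were assigned their peaks and 8 of 20 genes (40%) had one, with an odds ratio of 7.51 (2.66 to 20), an adjusted p of 0.00038 and a matched p of 0.024. Under the same change the cholinergic list reached 7 of 13 genes, Chat included, with an adjusted p of 0.00013 and a matched p of 0.0015. The axon guidance list then had 14 of 36 genes and a matched p of 0.079. Among the 1227 peaks with the highest scores, the motor neuron factors also passed Fisher's exact test (odds ratio 8.49, 2.06 to 26.4, adjusted p = 0.017, matched p = 0.123 after adjustment), as they did with peaks within 10 kb (adjusted p = 0.038) or 100 kb of a start (0.040). In a version added after the data were seen, without Isl1, the list had 3 of 19 genes (odds ratio 3.42, exact test, adjusted p = 0.157), and 7 of 19 with protein-coding genes alone (6.57, adjusted p = 0.0019, matched p = 0.066). Among the 1227 peaks it then gave 6.36 (exact test, adjusted p = 0.080). Of the lists that had passed, only axon guidance still did so among those 1227 peaks (odds ratio 9.74), whereas pluripotency, cholinergic transmission and housekeeping did not (odds ratios 5.65, 6.16 and 6.79, exact test, adjusted p = 0.080, 0.135 and 0.070), and 0 lists passed the matched test. In the top-scoring 25% of peaks, pluripotency passed both tests again (odds ratio 11, exact test, adjusted p = 0.018, matched p = 0.048), as did the motor neuron factors (16.6, adjusted p = 0.0030, matched p = 0.030, or 0.127 without Isl1).

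The remaining lists did not pass. JAK-STAT pathway genes had a peak in 4 of 30 cases (13.3%, 3.76 to 30.7), with an odds ratio of 2.80 (0.711 to 8.10) and an adjusted p of 0.147. Lifr, the LIF receptor gene, had the strongest (score 143.19, rank 35, 184 tags, intergenic, 13.8 kb upstream at chromosome 15, 7065556 to 7066055). Pim1 (57.81, 4 peaks), Il6st (48.98, -75.55 kb from its start), which encodes the shared gp130 receptor subunit, and Jak3 (31.58) followed, while Stat2 had none. Spinal interneuron factors had 4 of 27 genes (Lhx5 80.29, Lbx1 65.57, Barhl1 35.33 and En1 30.24, with none at Vsx1). Motor column and pool genes had 3 of 21 (Gfra3 76.82, Pou3f1 32.92 and Aldh1a2 30.51, with none at Hoxa5 and Hoxc5). There were 2 of 17 in glia (Nfib 55.67 and Slc1a3 42.56), 2 of 34 in ion channels and synapse (Cacna1a 58.62 and Syt1 32.92), and 1 each in the Notch (Rbpj 39.34), retinoic acid (Stra6 91.8) and endoderm and liver (Apob 119.1) lists. Blood genes and skeletal muscle genes had 0 of 16 each, which allows up to 20.6%. The peaks of no list differed in ChIP score from other peaks after adjustment. The lowest adjusted p was 0.226, and at an unadjusted p under 0.05 the motor neuron factors were higher (median 59.15, permutation p = 0.019) and the JAK-STAT genes lower (median 32.65, exact p = 0.042).

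**Figure D1:**
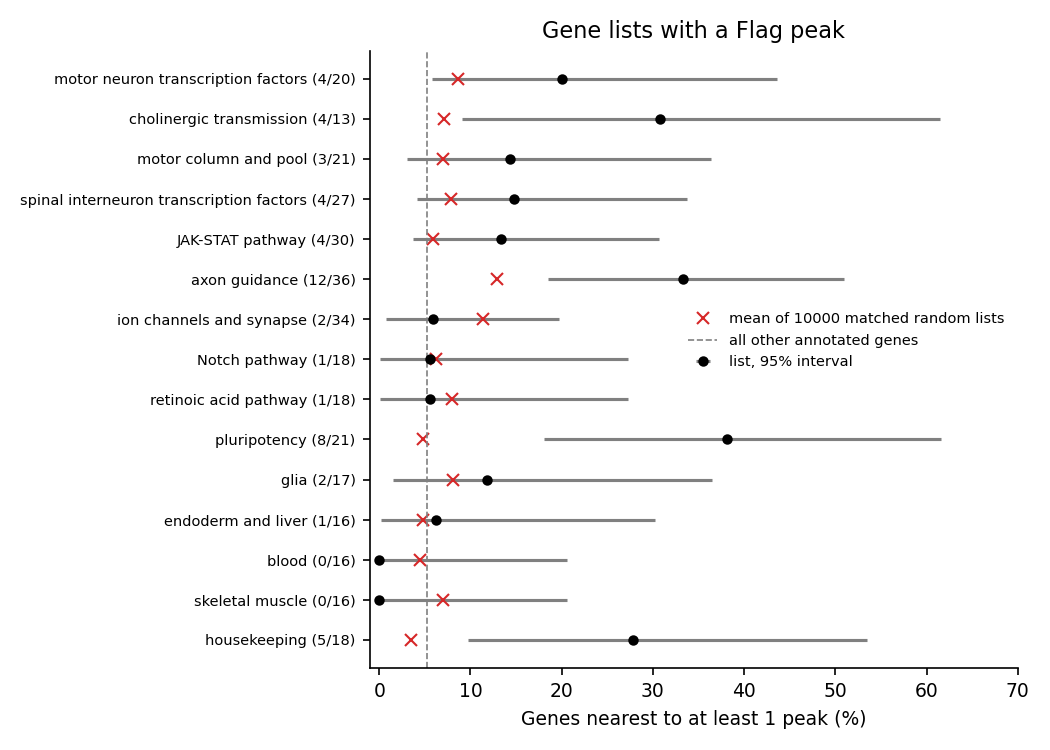
Percent of genes nearest to at least 1 peak in each of 15 lists (points, with 95% exact intervals and the counts beside the names), the mean of 10000 random lists matched on territory (crosses) and the percent among other genes (dashed line). The pluripotency (38.1%), axon guidance (33.3%), cholinergic (30.8%) and housekeeping (27.8%) lists lay highest, and blood and skeletal muscle lay at 0.

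Peaks lay nearer to genes than random positions did. Those positions were drawn from all known bases. Whether tags could be placed uniquely there was not allowed for, which may account for part of the differences. Transcription starts had 26.8% of peaks within 5 kb (25 to 28.6), against 16.7% of random placements, and 9.13% within 1 kb against 4.22% (permutation p = 0.002 for both, the smallest that 1000 placements can give). Introns held 45.4% of peaks against 38.6% (permutation p = 0.002), intergenic sequence 50.8% against 57.9% (p = 0.002), and exons 3.87% against 3.48% (p = 0.31). Peaks also came in groups: 21.2% (19.6 to 22.9) had another peak within 10 kb, against 2.07% of random placements (permutation p = 0.002). Part of this came from regions with several maxima, since with 1 peak kept per region, an alternative chosen after the data were seen, the share was 11.3% (10.1 to 12.7) against 1.91% (permutation p = 0.002). By peaks assigned to the nearest of all annotated genes, Sall1, a zinc-finger gene, had most (7 in 4 regions), followed by Gm15975 (6 in 2), Spry2 (6 in 5), Akap2 (5 in 4) and SNORA17 (5 in 4), with genes tied at 5, Esrrb among them, ordered by their strongest peak. With protein-coding genes alone, Spry2 had 11 peaks and Sall1 had 7. In all, 96 genes had 3 or more peaks against 36.6 at random (permutation p = 0.002), and 53 did with 1 peak kept per region.

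Chromosomes differed in their number of peaks. Chromosome 14, which held the 2 strongest peaks and Chat, had 186 peaks against 116 expected from its length (ratio 1.61, 1.39 to 1.84, exact binomial test, adjusted p = 6.8e-09). Chromosomes 8, 11, 17 and 19 also had more (ratios 1.30, 1.48, 1.33 and 1.52). Chromosome X had 34 peaks against 154 expected (ratio 0.221, 0.153 to 0.308, exact test, adjusted p = 2.7e-31), and chromosomes 1, 3 and 7 had fewer too (0.828, 0.739 and 0.723). Only chromosomes 7, 8, 14 and X kept their call when the share of annotated genes or of protein-coding genes, the latter added after the data were seen, replaced length. By these gene shares chromosome 11 turned to 0.859 and 0.921, chromosome 1 to 1.18 and 1.11, and chromosome 3 to 1.02 and 0.940, none of them called. Chromosome 17 fell to 1.13 and 0.977, neither called, and chromosome 19 to 1.36, still called, and 1.08, not called. Chromosome Y had 0 peaks against 14.7 expected from its length (adjusted exact p = 4.2e-06), but most of its sequence is unknown: 2.59 were expected from its 2.70 Mb of known bases (adjusted exact p = 0.416), and 1.38 or 1.87 from the gene shares. The p-values against length and gene shares were adjusted over 21 chromosomes, and the value for the known bases of chromosome Y over 276 windows of 10 Mb. The tests counted each peak as independent, although peaks came in groups, so their intervals are too narrow and their p-values too small. With 1 peak kept per region, an alternative added after the data were seen, the same chromosomes were called against length. Groups of neighbouring regions were still not allowed for there.

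**Figure D2:**
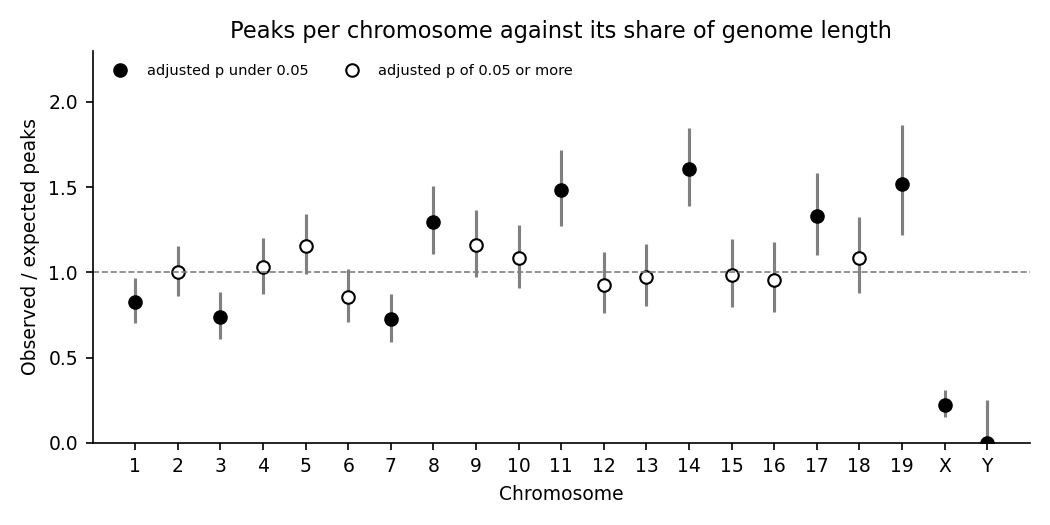
Ratio of observed to expected peaks on each chromosome (vertical axis, from 0) with 95% intervals; filled points passed an adjusted p of 0.05. Chromosome 14 was highest at 1.61, and chromosome X (0.221) and chromosome Y (0) were lowest.

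Homeodomain sequence marked the peaks. The core TAATTA, a site bound by LIM-homeodomain factors, was present in 34.3% of 200 bp windows centred on the maxima (32.4 to 36.2) against 6.5% of flanks, an odds ratio of 7.51 (6.51 to 8.68, Fisher's exact test, adjusted p = 2.2e-196). The shorter core ATTA was in 94.2% against 66.7%. The octamer ATGCAAAT, which POU factors bind, was in 4.24% against 1.57% (odds ratio 2.78, 2.04 to 3.79, exact test, adjusted p = 1.3e-10). The E-box CAGCTG (13.9% against 8.92%), the SOX site ATTGTT (14.3% against 10.7%), the Onecut site ATYGAT (11.2% against 7.91%) and the CTCF core (1.22% against 0.469%) were also more frequent. Altogether 8 of 18 motifs passed upward and 0 downward. The Onecut call was lost against dinucleotide-shuffled peak sequence (odds ratio 1.08, exact test, adjusted p = 0.46), against which a scrambled homeodomain control passed as well (2.01). Mean GC content was 48.2% in peaks and 44.9% in flanks.

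**Figure D3:**
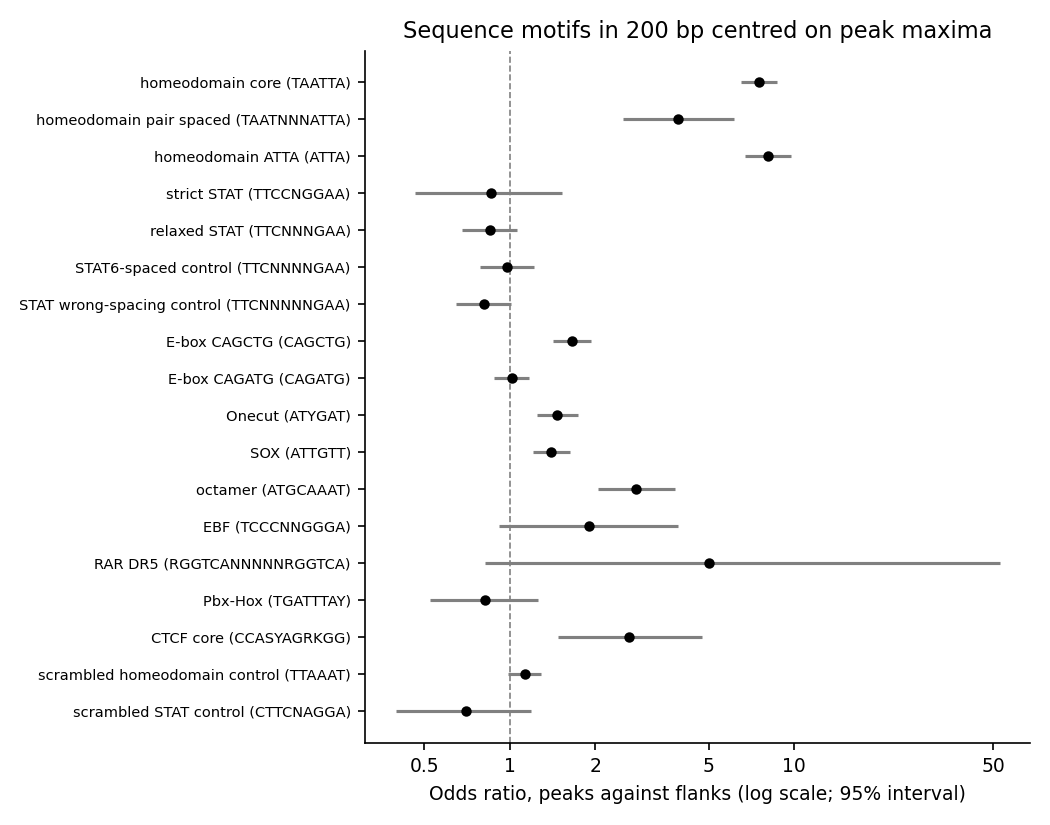
Odds ratios (log axis) with 95% intervals for 18 motifs in the 200 bp at peak maxima against flanks. The homeodomain motifs TAATTA (7.51) and ATTA (8.05) lay far to the right of 1, and the relaxed STAT motif (0.850) did not.

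The series title names STAT3 beside the LIM complex, so STAT sites were counted in the same windows. The relaxed STAT site TTCNNNGAA was in 5.01% of peaks (4.18 to 5.95) and 5.85% of flanks, an odds ratio of 0.850 (0.678 to 1.06, exact test, adjusted p = 0.20). The strict site TTCCNGGAA was in 0.733% against 0.856% (odds ratio 0.856, 0.463 to 1.52). The wrong-spacing control gave 4.97% against 6.05%. Pairs of TTC and GAA had odds ratios from 0.633, with 10 bases between, to 0.977, with 4. A small excess of STAT sites could be masked by this general shortage at peaks. Among peaks with TAATTA, 4.63% had a relaxed STAT site, against 5.21% of peaks without (odds ratio 0.884, 0.582 to 1.32, Fisher's exact p = 0.56). The Lifr, Lhx3, Mnx1 and Chat peaks named above had no relaxed STAT site, and the stronger Isl1 peak had one.

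**Figure D4:**
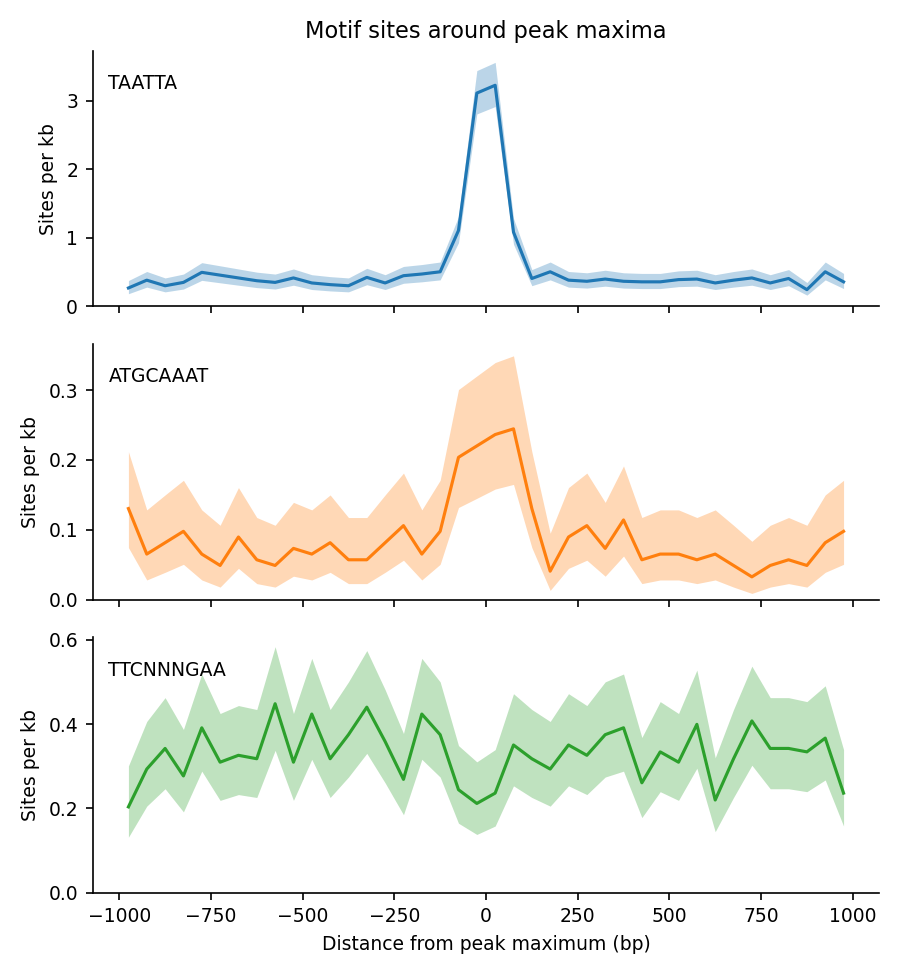
Sites per kb in 50 bp steps within 1000 bp of the peak maxima for TAATTA, ATGCAAAT and TTCNNNGAA, with 95% Poisson bands and separate vertical axes from 0. TAATTA rose to 3.23 sites per kb beside the maximum, ATGCAAAT reached 0.244, and TTCNNNGAA showed no rise at the maximum (0.236).

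Peak strength went with the homeodomain core only slightly. Peaks with TAATTA had a median ChIP score of 42.4 against 40.2 for those without (permutation p = 0.0024), and by ChIP tags the medians were 33 and 31 (permutation p = 0.097). TAATTA was present in 36.7% (32.9 to 40.7) of the highest-scoring 25% of peaks and 30.6% (26.9 to 34.4) of the lowest. Of the 10 strongest peaks 1 had it, the one near Gm11828, but 10 peaks are few and their share was not tested against that of other peaks. Peaks with a relaxed STAT site had a median score of 40.7 against 40.95 (permutation p = 0.86).

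Pairs of TAAT and ATTA cores, counted after the data were seen, had preferred spacings. ATTA followed by TAAT had its highest odds ratios with 3 bases between (4.93% against 0.632% of flanks, odds ratio 8.16, 5.44 to 12.6) and with 10 (2.93% against 0.346%, odds ratio 8.69, 5.06 to 15.8), and with 2 bases it was in 3.55% of peaks (5.12). TAAT repeated in the same direction was in 6.81% of peaks with 0 bases between (odds ratio 6.33, 4.63 to 8.76) and in 6.03% with 5 (5.10, 3.74 to 7.02). With 0 bases between, this repeat contains TAATTA, which was itself more frequent at peaks (odds ratio 7.51). The repeat was in 167 of the 842 peaks and 56 of the 319 flanks with TAATTA. Its odds ratio is therefore not set apart from that of the core and shows no preferred spacing by itself. TAAT followed by ATTA had an odds ratio of 5.57 with 2 bases between and 0.181 (0.0206 to 0.738) with 0.

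**Figure D5:**
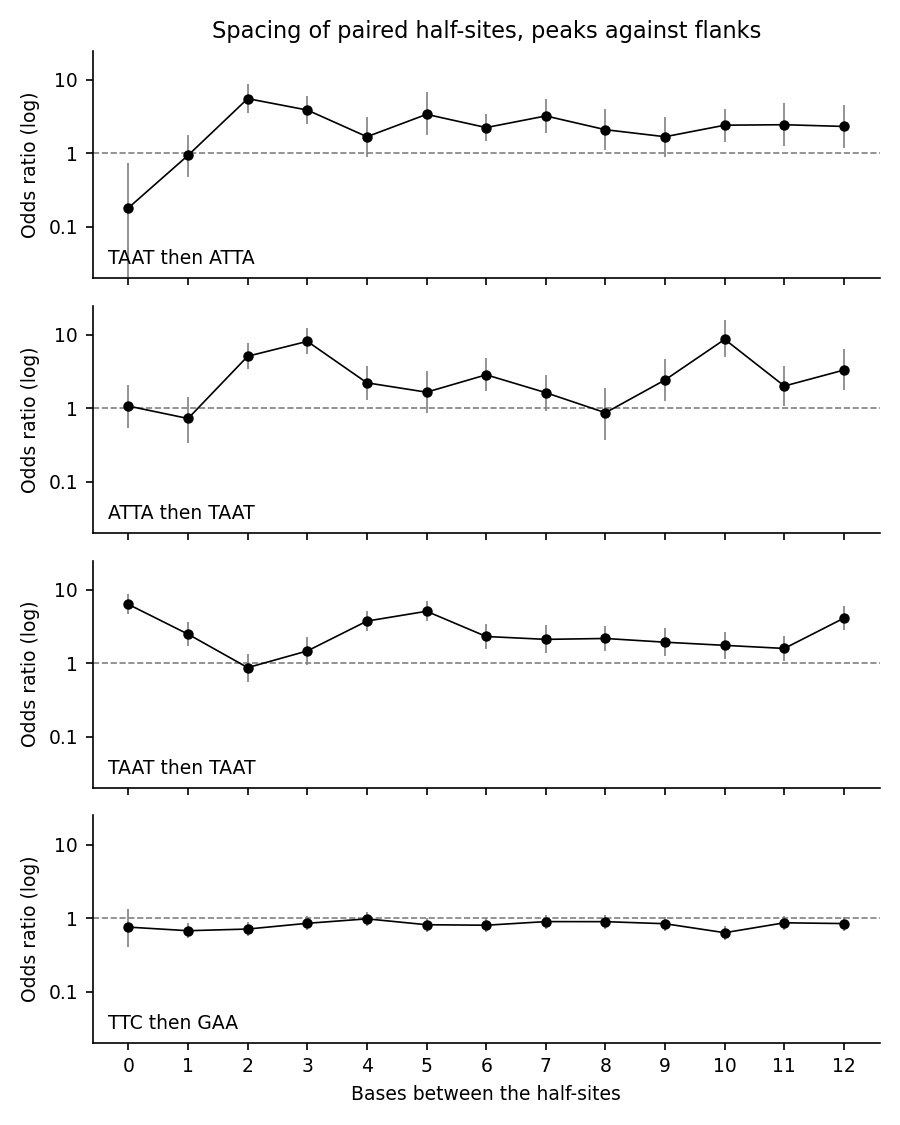
Odds ratio (log axis, 95% intervals) of paired cores in peaks against flanks by the number of bases between them, for 3 TAAT and ATTA arrangements and for TTC with GAA. The arrangement ATTA then TAAT had maxima at 3 (8.16) and 10 bases (8.69), while TTC with GAA stayed at or below 0.977 at each spacing.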

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

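The values with 1 peak per region, with a background score under 10%, with protein-coding shares per chromosome and without Isl1 were chosen after the data were seen. No paired analysis was possible because the list holds no value per set or library. For the same reason the 50% overlap between sets, the ratio within each set and the versions without a set were not run, and an odds ratio that was infinite has no value. Of the values that answer a comparison, 75 kept their direction and side of the threshold or stayed within their limits, 12 moved beyond them, 2 turned and 1 fell short of the threshold. TAATTA stayed enriched in each alternative (odds ratio 4.11 to 17), the relaxed STAT motif never passed (0.768 to 0.912), and the ratio was 1.5 to 1.78 on chromosome 14 and 0.199 to 0.333 on chromosome X. The 50% of peaks with the highest scores, 1227 peaks, left 96.7% at 10 times background, 3 chromosomes with more and 3 with fewer peaks, 26 genes with 3 or more peaks, 2 lists past Fisher's test and 0 past the matched test. Adding 1 to each score gave 88.5%, protein-coding shares gave 4 chromosomes with more peaks (8, 12, 14 and 18) and 3 with fewer (2, 7 and X), annotated-gene shares gave 7 and 4, and 1 peak per region gave 53 genes with 3 or more. By ChIP tags 1 list passed for strength, the motor neuron factors (median 104 against 31, adjusted p = 0.00013 by permutation), whose 4 Neurog2 peaks share 1 region and so 1 count; with 1 peak per region it did not (53 against 30, exact p = 0.082). The TAATTA strength ratio by tags was 1.06 (permutation p = 0.097). Against shuffled sequence 1 motif, the scrambled STAT control, was less frequent (0.496). Directions turned as follows. Chromosomes not called by length turned with a call by annotated-gene share (2 at 0.705, 4 at 0.785 and 15 at 1.28) and by protein-coding share (2 at 0.830 and 12 at 1.35). Turned without a call were, by annotated-gene share, 1 (1.18), 3 (1.02), 11 (0.859), 12 (1.19), 13 (1.20) and 16 (1.22), by protein-coding share 1 (1.11), 4 (0.996), 9 (0.958), 11 (0.921), 13 (1.14), 15 (1.07), 16 (1.18) and 17 (0.977), in the 1227 peaks 2 (0.976) and 15 (1.02), with 1 peak per region 2 (0.990), 15 (1.03) and 16 (1.01), and with low background 15 (1.03). No list or motif that turned was called in the new direction. Strict STAT gave 1.24 in 500 bp and 2.01 against shuffled sequence, where the 4-base and 5-base STAT controls gave 1.03 and 1.04 and Pbx-Hox 1.53. In the 1227 peaks the 4-base control gave 1.09, Pbx-Hox 1.05 and the Notch list 0, as in the top-scoring 25%. With low background the 4-base control gave 1.01. CAGATG gave 0.990 in 500 bp and 0.988 with 1 peak per region, and the scrambled STAT control 1.03 in 500 bp. Within 10 kb of a start the motor column, ion channel, glia and endoderm lists gave 0. With protein-coding genes the retinoic acid list gave 0.660, endoderm 0.749 and skeletal muscle 1.60. The causes were not tested. Other single values moved past the threshold in 15 cases and short of it in 16. The motor neuron list passed Fisher's exact test in 8 of these, with adjusted p = 0.017 in the 1227 peaks, 0.0030 in the top-scoring 25%, 0.047 with low background, 0.00038 with protein-coding genes, 0.038 within 10 kb, 0.040 within 100 kb, and, without Isl1, 0.0019 with protein-coding genes and 0.018 in the top-scoring 25%; EBF sites in 500 bp and 2 scrambled controls against shuffled sequence, chromosomes 5 and 10 by annotated-gene share and 18 by both gene shares were the rest. Those lost were pluripotency in the 1227 peaks alone (5.65), cholinergic (6.16, 5.49) and housekeeping (6.79, 8.25) in both sets of stronger peaks, axon guidance within 10 kb, Onecut, and chromosomes 1, 3, 7, 17, 19 and Y in 1 or 2 settings each. Unknown depth per library limits each count.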

Other observations

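The tests of regions per gene, of 6-mers, of 10 Mb windows, of part of chromosome 14, and, for pluripotency genes, of peaks with a high background score and of octamer sites per gene were chosen only after the data were seen. The matched test on territory was part of the fixed plan and is the one given in the results. The other tests of explanations were chosen after their pattern had been seen and before their own values were.

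Spry2, a feedback inhibitor of receptor tyrosine kinase signalling, had 10 separate peak regions in its 206 kb territory among protein-coding genes, where 0.179 were expected (adjusted p = 1.7e-10, exact binomial test over 22333 genes). Of the 11 genes past the test, Pim1, a kinase gene induced by STAT signalling, had 4 regions (0.0621 expected), Esrrb 5 (0.251) and Akap2 4 (0.149). Acly, Bcl2l1, which encodes an inhibitor of apoptosis, Nfatc3, Slc7a7 and Ssr2 had 3 each, Kif13b had 5 and Gm10322 had 4. The strongest Spry2 peak had a score of 80.03, and the best Pim1 peak had 57.81 and lay -23.2 kb from its start. The expected counts used 1 rate for the whole genome, so neither the grouping of peaks nor the excess on chromosome 14 was allowed for. Spry2, Kif13b and Slc7a7 lie on chromosome 14. The median background score at their peaks was 3.21%, 8.26% and 6.33% of the ChIP score, against 0.722% across the list. Genes of this paragraph other than Spry2, Pim1, Esrrb, Akap2 and Acly were chosen after their values were seen.

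Among 2080 6-mers, 549 were more frequent at peaks than in flanks and 444 less frequent. Among the more frequent, TAATTA led, followed by AATTAG (34.8% against 8.82%) and CAATTA (30.2% against 7.60%). Of 6-mers without ATTA, TAAT or AATT, AGCAGG (31.3% against 16.7%), CAGCAG (31.9% against 18.3%) and TGCTAA (19.5% against 9.19%) led among those more frequent at peaks, and AAAAAT (8.35% against 23.8%) was depleted with a smaller p than these. TGCTAA overlaps GCTAAT, which holds TAAT (25.5% against 6.11%), so it is not set apart from the core. The higher GC content of peaks (48.2% against 44.9% in flanks) was not allowed for in these counts. The peaks with the highest background scores lay at Ly6c2 on chromosome 15 (score 137.57, background 44.21) and near Sfi1 on chromosome 11 (103.31 and 33.15, 491 tags), genes chosen after their values were seen.

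Pluripotency genes such as Esrrb, Prdm14 and Zfp42 held peaks more often than other genes. Large territories were argued against, since random lists matched on territory rarely did as well (permutation p = 0.00020, the smallest that 10000 lists can give). This is the matched test already given above, before adjustment, and not a further test. Peaks with a background score of 10% or more of the ChIP score were argued against as the whole cause, since without these 133 peaks, whose removal left 87 other genes without a peak, 8 list genes kept a peak and the odds ratio was 11.8 (4.24 to 30.8) against 11.2, while background that this score does not measure stays open, because no ratio in the list exceeds 0.325 and the median of 0.0142 (0 to 0.0331) at the list's 13 peaks decides nothing. An exact octamer ATGCAAAT at most of the bound genes was argued against as the whole cause. At a peak, 0 of the 8 genes had one (at most 36.9%), where 87.3% would be needed for the excess over matched lists. Octamer sites that differ from this sequence were not counted and stay open. TAATTA was in 30.8% of the list's peaks (9.09 to 61.4) against 34.3% of others, which decides nothing, because the interval includes the others' share. Accessible chromatin shared with housekeeping genes may also contribute and was not tested. Whether the fusion acts on these genes was not tested, because the list holds no value per library and so no comparison of with Dox against without Dox.

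Chromosome X held 34 peaks, far below its share of length. Fewer genes on X were argued against, because the count stayed at 0.333 (0.231 to 0.463) of that expected from protein-coding genes. So were fewer TAATTA sites, which were 1.13 times as dense on X as on autosomes while its peak ratio was 0.208 (0.144 to 0.291). A single X copy that lowers peak heights 2 times remains a candidate explanation: with autosomal scores divided by 2, 30.5 X peaks were expected, inside the interval of the observed count (23.5 to 47.5). That number takes scores to be proportional to copy number, which could not be checked because their scaling is not given. The number of X copies in these cells was not measured here, and no explanation beyond those above was tested.

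Chromosome 14 held more peaks than its length. Dense clusters were argued against as the whole cause (ratio 1.38, 1.16 to 1.63, with 1 peak per 100 kb). The predictions for an extra copy take scores to be proportional to copy number, which could not be checked because their scaling is not given. If so, an extra copy of the whole chromosome predicts 1 for the count at 1.5 times the lowest score. The value found, 0.613 (0.480 to 0.770), argued against such a copy only under that assumption. The chromosome's mean background score, 1.56 times (1.33 to 1.82) that of other autosomes, met the 1.5 that an extra copy predicts. The part from 60 to 120 Mb had 2.17 peaks per Mb against 0.859 in the rest of the chromosome and 0.952 on other autosomes, but unevenly: its windows from 60, 70 and 100 Mb, the last with Spry2, had 28, 40 and 35 peaks, those from 80 and 110 Mb had 7 each, and outside it the window from 50 Mb had 24 (9.59 expected in each). For an extra copy of that part the same count gave 0.876 (0.650 to 1.15), which meets the prediction, but its background ratio of 1.82 (1.53 to 2.14) lay above the predicted 1.5, so a single gain in all cells was not borne out in full. A gain of another size, which could also raise the count near Spry2, stays open, and no explanation beyond those above was tested.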
